A study of Mus musculus with 3 samples.

How the data were processed

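The series holds 3 RNA-seq libraries from primary hepatocytes of C57BL/6 mice, 1 from cells given the solvent DMSO and 2 from cells given tauroursodeoxycholic acid (TUDCA). Per the labels' protocols, hepatocytes were isolated by perfusing the liver with collagenase and plated on gelatin in serum-containing medium with insulin. Polyadenylated RNA was captured on oligo(dT) beads, copied from random primers and fragmented by nebulisation, per the labels' protocols. The strand setting of the counting is not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart.

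The authors deposited RPKM values (reads scaled by gene length and by the reads of the library), 1 table per library with 37620 Ensembl gene identifiers each. The submitters' processing notes name CASAVA, TopHat2 2.0.7, Bowtie2 and HTSeq, without their roles or order. The genome build and the gene annotation are not given in the sources used here, and the tables hold no coordinates, so no genomic positions are printed. Symbols were taken by identifier from GENCODE release M21 and matched 32897 of the 37620 identifiers, including 11149 of the 11300 genes tested.

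The RPKM values kept the read numbers. For each of the 19146 genes above 0 in at least 1 library, a gene length gave whole reads in all 3 libraries, within 1e-09 reads, at library totals of 10774289 reads for DMSO, 9757547 for TUDCA replicate 1 and 10575699 for TUDCA replicate 2. The smallest such whole numbers added up to 95.7 to 95.8% of those totals. A gene may hold a multiple of the reads and of the length used here, and the source of the gap was not tested. The voom fit, the filter at 300 nt and 20 reads, the length correction and the simulated reads all use these smallest values. So does the closing count of keratinocyte genes with fewer than 3 reads in DMSO. A read over a gene of 1 kb was worth 0.0928 RPKM in the DMSO library, 0.1025 in TUDCA replicate 1 and 0.0946 in TUDCA replicate 2. All other tests were run on the RPKM values.

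Values were tested as log2(RPKM + 1), so fold changes of low genes are understated. Genes with a mean of at least 1 RPKM over the 3 libraries were kept, which left 11300. The comparison of TUDCA with DMSO was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean), with Benjamini-Hochberg adjustment and a threshold of 0.05. The only residual degree of freedom came from the pair of TUDCA libraries, and the lone DMSO library was assumed to vary like them. At this filter limma estimated infinite prior degrees of freedom, so each gene was given the common spread at its expression level (SD of 0.159 to 0.265 on the log2 scale) in place of its own. A rule of size without a test was set beside it, a log2 fold change of at least 1 in the same direction in both TUDCA libraries. Because both comparisons used the same DMSO library, values expected with no effect were simulated 100 times from the spread between the TUDCA libraries.

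Before the data were examined, 31 gene lists, the rule for named genes, the tests and most alternatives were fixed. Of 748 list entries, 741 matched an identifier, 9 of them through an older symbol. The named genes are first the 12 highest and 12 lowest called genes, ranked by the smaller of both libraries' fold changes. This ranking skipped genes without a symbol and symbols that start with Mir, Snor, or Gm or LOC and a digit, or that hold Rik. Then come up to 4 members of each list with the largest mean fold change, and Cyp7a1, Nr0b2, Abcb11, Slc10a1, Hspa5, Ddit3, Atf4, Xbp1 and Alb. Some genes that this rule takes in are not reported here. Lists with at least 5 measured members were tested with limma's camera (competitive test against the other genes, preset correlation of 0.01) and adjusted over 30 lists. Each list's median was also ranked among 10000 random lists matched on expression. Lists of BMP-SMAD targets and of epidermal keratinocyte genes were chosen after seeing the data and serve only the closing tests.

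On simulated reads with the real depths, the fit of TUDCA against DMSO over 11300 genes called 76% of 100 genes changed 2-fold and 96% of 100 genes changed 4-fold, each in the right direction. It also called 38 unchanged genes, 18.1% of all calls, and 34 of these were under 300 nt or under 20 reads by those values. A separate fit of only the 10677 simulated genes over both limits called 19 unchanged genes, 9.3% of its calls. Both shares lie above the threshold of 0.05. The simulated reads had the same dispersion for all genes and libraries, DMSO included, and only genes over 20 reads were changed. The rates of false and true calls may therefore be too favourable for data whose spread differs between genes.

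The alternatives were a pseudocount of 0.1, no filter, a filter at 5 RPKM, rescaling to TPM, quantile normalization, median centring, limma without the trend, with robust estimation or against a fold change of 1.5, a threshold of 0.1, a size limit of 0.58, camera with an estimated correlation or with ranks, and leaving out each TUDCA library. Added after seeing the data were a correction for GC content and gene length, a filter at 300 nt and 20 reads, a filter at 0.3 RPKM, and voom with limma on the recovered reads. Scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.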

Results

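Gene expression was measured by mRNA sequencing in primary mouse hepatocytes, liver parenchymal cells that lose part of their liver programme in culture. TUDCA is a bile acid conjugated to taurine that is also used as a chemical chaperone, and the comparison asked which genes it modulates relative to the solvent DMSO. The labels give TUDCA at 100 mM for 24 h and no time for DMSO. A difference in time between the cultures therefore cannot be told apart from an effect of TUDCA. The dose is printed as labelled and was not checked against another source, so an error of its unit is possible. There was 1 DMSO library and there were 2 TUDCA libraries, with totals of 10774289, 9757547 and 10575699 reads behind the RPKM values. The series describes 2 independent experiments without assigning libraries to them, so the spread between the TUDCA libraries may be technical. The limma p-values and SE at the filter of 1 RPKM take this spread pooled over genes of similar expression, not each gene's own. For a gene whose TUDCA libraries differ widely, they are too small. All values for DMSO come from 1 library without a replicate. TUDCA values are means ± SD of n = 2 or, where given as a pair, those of TUDCA replicates 1 and 2 in that order, and log2 fold changes are on the log2(RPKM + 1) scale ± SE.

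Both TUDCA libraries lay farther from the DMSO library than from each other. Over 11300 genes the SD of the log2 differences from DMSO was 0.414 for TUDCA replicate 1 and 0.365 for TUDCA replicate 2, against 0.316 between the TUDCA libraries. The Pearson correlations across genes, which are not independent replicates, were 0.980 and 0.984 with DMSO and 0.988 within TUDCA. More than 2-fold differences from DMSO were seen for 2.51% and 1.66% of genes, and for 0.67% between the TUDCA libraries. The fold changes of both TUDCA libraries had a covariance of 0.102. In simulation the shared DMSO library gave 0.050, a difference of 0.052, if DMSO varied only as much as the TUDCA pair. The correlation of the fold changes was 0.677 against 0.500 simulated, and 70.9% of genes had the same sign against 66.5%. Extra variation of the single DMSO culture would raise the measured values too, so the excess cannot be assigned to TUDCA.

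The largest rises under TUDCA included Id2 (ENSMUSG00000020644), a helix-loop-helix protein that lacks a DNA-binding domain, which rose from 17.8 RPKM in DMSO to 120.5 ± 30.3 (log2 fold change 2.67 ± 0.22, limma adjusted p = 4.4e-30). Gstm3, a glutathione S-transferase, rose from 5.40 to 30.2 and 79.2 RPKM, and Pck1, the cytosolic enzyme of gluconeogenesis that makes phosphoenolpyruvate, rose from 0.354 to 5.03 and 10.6 RPKM. Without TUDCA replicate 2 their log2 fold changes were 2.29 and 2.15 in place of 2.97 and 2.63. Pck1 had only 7 reads in the DMSO library, as the smallest whole number that fits. The hepcidin genes Hamp (ENSMUSG00000050440), which encodes the iron-regulating hormone, and Hamp2 rose from 486.1 RPKM to 3752 and 1866 RPKM and from 13.4 to 126.6 and 59.3 RPKM in the TUDCA libraries. Their log2 fold changes were 1.94 and 2.07 without TUDCA replicate 1 and 2.95 and 3.15 without TUDCA replicate 2. Serpina7 (thyroxine-binding globulin), Apoa5 (an apolipoprotein of triglyceride metabolism), Fmo5 (a flavin monooxygenase), Cdo1 (cysteine dioxygenase) and Abcb4 (the canalicular phospholipid transporter) rose to between 3.49 and 6.28 times DMSO. The largest falls included the epidermal genes Crct1 (ENSMUSG00000027913), from 801.9 to 119.7 ± 26.1 RPKM (log2 fold change -2.75 ± 0.20, limma adjusted p = 6.5e-38), Lce1g, from 43.7 to 4.78 ± 1.70 RPKM, Lce1h, from 9.86 to 0.290 and 0.134 RPKM, and Aloxe3, from 17.1 to 4.12 ± 1.15 RPKM. Xirp2, an actin-binding protein of striated muscle, fell from 8.79 to 0.781 and 0.349 RPKM, and the ubiquitin ligase Rnf183 from 5.355 to 0.552 and 1.309 RPKM. Without TUDCA replicate 1 the log2 fold changes of Lce1h, Xirp2 and Rnf183 were -3.26, -2.86 and -1.46, and without TUDCA replicate 2 they were -3.07, -2.46 and -2.03. The endoplasmic reticulum (ER) proteins Creld2 and Sdf2l1, the matricellular protein Ccn2, the kinase Plk3 and the actin crosslinker Flnc fell to between 0.297 and 0.389 of DMSO. The ranking also took in mt-Tt, mt-Ts2 and Npn2. The mitochondrial tRNA genes mt-Tt and mt-Ts2 had no read in DMSO and, as the smallest whole numbers that fit, 5 and 5 reads, and 2 and 3 reads, in the TUDCA libraries. Npn2 had 4.95 RPKM in DMSO and no read with TUDCA, and a gene above 0 in 1 library only leaves its number of reads open. voom on the smallest whole reads called none of these 3 genes (adjusted p = 0.0513, 0.289 and 0.0527), with 268 genes called in all. Hamp and Hamp2, Gstm3 and other mu-class genes, and Lce1g and Lce1h have close paralogs, so the split of reads between them is uncertain.

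In all, 299 of the 11300 genes passed the limma test at the 0.05 threshold, 200 higher and 99 lower with TUDCA, and 1216 had an unadjusted p below 0.05. Of the 299 genes, 297 had the same sign in both TUDCA libraries. Calling on the mean of these fold changes, with a shared DMSO library, largely fixed this, so it is no separate evidence. By the rule of size, 87 genes were higher and 32 lower in both TUDCA libraries. Simulation without an effect, with DMSO given the TUDCA spread, gave means of 13.1 and 12.8 and at most 25 in either direction. With 1 TUDCA library against DMSO, the rule of size passed 188 genes without TUDCA replicate 1 and 284 without TUDCA replicate 2. The count of 299 rests on the shared spread that limma assumed at the filter of 1 RPKM. It was 0 without the filter (19146 genes, 1696 with an unadjusted p below 0.05), 26 at a filter of 0.3 RPKM, 57 when tested against a fold change of 1.5 and 692 after correction for GC content and gene length, and all gene calls named here were lost without the filter. Genes given as called or not called, with no setting named, are so by limma at this filter. The GC and length correction also called list members that limma did not. It added 10 in the cell cycle list (higher, except Mcm2 and Mcm6) and 6 in the ATF4 and CHOP list (all lower). It added 4 each in the ER chaperone (lower, except Xbp1), NRF2 (lower, except Gsta1) and pericentral (higher, except Oat) lists. Any other list gained at most 3.

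**Figure D1:**
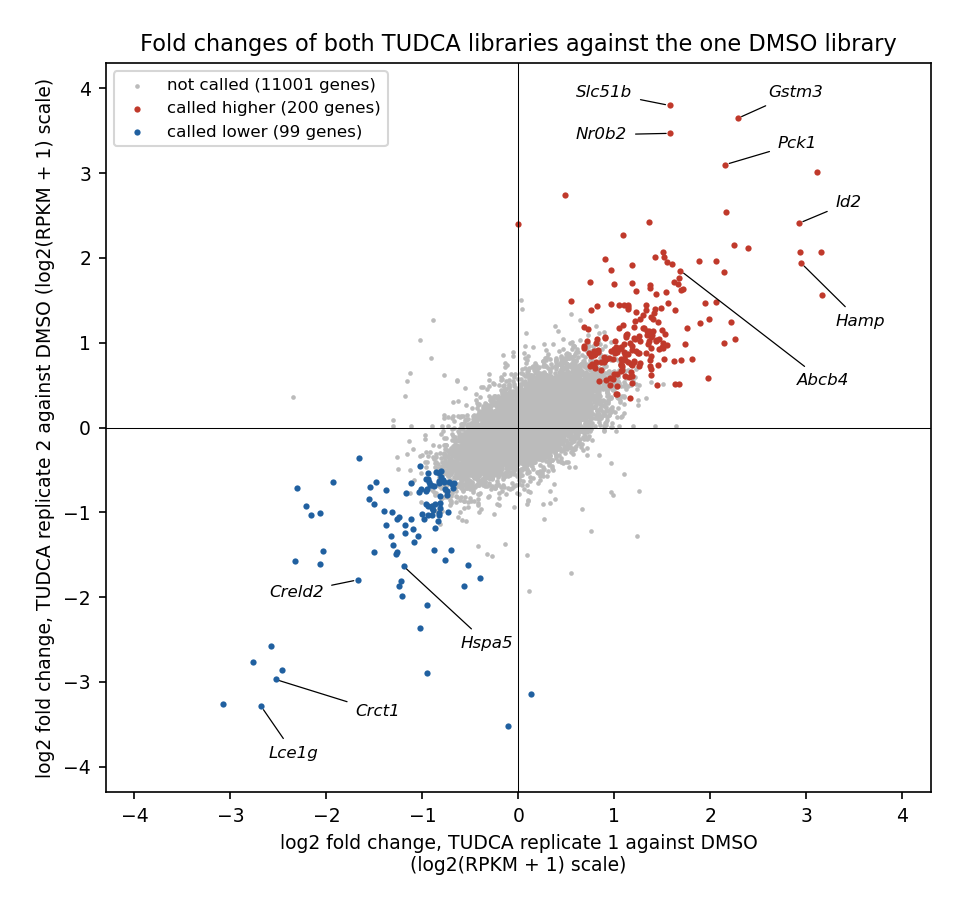
Log2 fold changes of TUDCA replicate 1 (x axis) and TUDCA replicate 2 (y axis) against the same DMSO library, on the log2(RPKM + 1) scale, 1 point per gene for 11300 genes. The 200 genes called higher (red) and the 99 called lower (blue) lie mostly in the quadrants of equal sign. The shared DMSO library by itself pulls points along that diagonal, and genes were called on the mean of both fold changes.

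Of 30 measured ER chaperones and folding factors, 9 were called lower with TUDCA, none higher and 21 were not called. Hspa5 (ENSMUSG00000026864), which encodes the main ER chaperone BiP, fell from 1807 RPKM in DMSO to 684.3 ± 146.3 (log2 fold change -1.42 ± 0.20, limma adjusted p = 1.9e-10). Creld2 fell from 172.1 to 51.0 ± 3.2 RPKM, Sdf2l1 from 162.9 to 57.7 ± 1.1 RPKM and the disulphide isomerase Pdia4 from 224.3 to 96.2 ± 12.1 RPKM. When adjusted over the list alone 12 were lower, and the fold change was negative for 28. The median log2 fold change was -0.38 (-0.32 and -0.49 in the 2 libraries, camera adjusted p = 2.3e-21, adjusted p = 0.421 with an estimated correlation). Xbp1, a transcription factor of the unfolded protein response, stood at 139.7 RPKM in DMSO and 191.7 ± 0.3 with TUDCA and was not called (log2 fold change 0.45 ± 0.20, limma adjusted p = 0.339), except after the GC and length correction (adjusted p = 0.0439).

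Of 22 measured genes of the ATF4 and CHOP branch of the unfolded protein response, 3 were called lower, none higher and 19 were not called. Ppp1r15a (GADD34, which directs dephosphorylation of eIF2-alpha) fell from 90.4 to 39.5 ± 8.1 RPKM, and Ddit3, which encodes the transcription factor CHOP, fell from 69.7 to 36.1 ± 1.2 RPKM (log2 fold change -0.93 ± 0.23, limma adjusted p = 0.00304). Herpud1, a factor of ER-associated degradation, fell from 137.7 to 83.9 ± 5.5 RPKM, a call lost with quantile normalization, without the variance trend and with voom (adjusted p = 0.124, 0.221 and 0.0544). The amino acid transporter Slc7a5 had 20.8 RPKM in DMSO and 11.9 ± 3.0 with TUDCA (limma adjusted p = 0.0968, called lower by voom and after the GC and length correction, adjusted p = 0.0432 and 0.0129). Atf4 itself had 224.8 and 199.3 ± 21.5 RPKM (adjusted p = 0.880). When adjusted over the list alone 8 were lower, and 21 had a negative fold change. The median log2 fold change was -0.46 (-0.55 and -0.41 in the 2 libraries, camera adjusted p = 1.0e-10, adjusted p = 0.455 with an estimated correlation).

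Among 19 measured genes of bile acid transport and targets of the bile acid receptor FXR, 6 were called higher, none lower and 13 were not called. Slc51b (ENSMUSG00000053862), a subunit of the basolateral bile acid exporter, had 1.52 RPKM in DMSO and 6.51 and 34.1 RPKM in the TUDCA libraries (log2 fold change 2.69 ± 0.28, limma adjusted p = 4.0e-18). Nr0b2 (ENSMUSG00000037583), the corepressor SHP that FXR induces, had 1.15 RPKM in DMSO and 5.43 and 22.8 RPKM with TUDCA (log2 fold change 2.53 ± 0.29, limma adjusted p = 4.4e-15). These libraries differed widely, so without TUDCA replicate 1 the log2 fold changes were 3.80 and 3.47 and without TUDCA replicate 2 they were 1.57 and 1.58, and robust estimation called neither gene (adjusted p = 0.880 and 0.855). In the DMSO library Slc51b had 8 reads and Nr0b2 14, as the smallest whole numbers that fit. Abcb4 rose from 31.6 to 110.2 ± 8.9 RPKM, and Nr1h4, which encodes FXR, rose from 6.26 to 14.9 ± 4.2 RPKM. The canalicular bile salt pump Abcb11 had 3.29 RPKM in DMSO and 4.50 ± 0.22 with TUDCA, and the uptake carrier Slc10a1 had 4.06 and 4.80 ± 1.02 RPKM, neither of them called (limma adjusted p = 0.788 and 0.931). With adjustment over the list alone 9 were higher, and the median log2 fold change was 0.58 (camera adjusted p = 1.3e-15, adjusted p = 0.421 with an estimated correlation).

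In the list of bile acid synthesis and conjugation, the conjugating enzyme Baat rose from 2.03 to 8.83 and 4.25 RPKM (log2 fold change 1.25, and 0.79 without TUDCA replicate 1) and Akr1c6 from 2.57 to 6.22 ± 1.86 RPKM, the latter a call lost with quantile normalization and with voom (adjusted p = 0.120 and 0.160). Cyp7a1, the rate-limiting enzyme of the classical pathway, had no read in any of the 3 libraries, so a change was not detectable at this depth. Of 12 measured members, 2 were called higher, none lower and 10 were not called, with 3 higher and 1 lower when adjusted over the list alone. The list as a whole did not pass (median log2 fold change 0.21, camera adjusted p = 0.0972), its median was 0.05 without TUDCA replicate 1 and 0.40 without TUDCA replicate 2, and it passed with quantile normalization (adjusted p = 0.043).

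**Figure D2:**
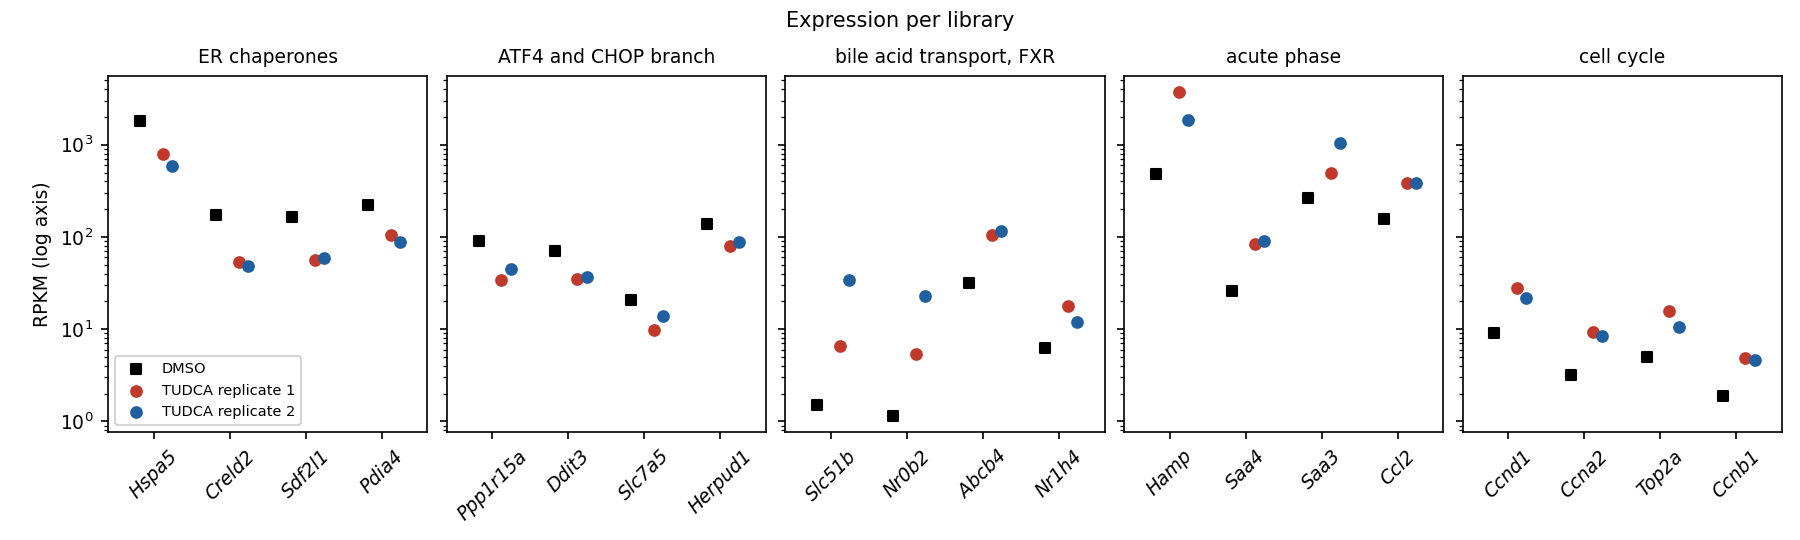
RPKM (log axis) of 4 named genes from each of 5 gene lists, 1 point per library, with DMSO as black squares, TUDCA replicate 1 in red and TUDCA replicate 2 in blue. Hspa5 fell from 1807 RPKM in DMSO to 788 and 581 RPKM with TUDCA, and the TUDCA points of Slc51b and Nr0b2 lie far apart.

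Among 30 measured acute phase and inflammation genes, 14 were called higher, none lower and 16 were not called. Besides Hamp, from 486.1 RPKM in DMSO to 3752 and 1866 RPKM with TUDCA, the serum amyloid genes Saa4 (25.7 to 87.0 ± 4.2 RPKM) and Saa3 (265.3 to 497.2 and 1051 RPKM, log2 fold change 1.44, and 0.90 without TUDCA replicate 2) and the chemokine Ccl2 (158.2 to 385.2 ± 2.8 RPKM) rose. With adjustment over the list alone 15 were higher, and 26 fold changes were positive and 4 negative. The median log2 fold change was 0.54 (0.64 and 0.49 in the 2 libraries, camera adjusted p = 3.1e-24, adjusted p = 0.421 with an estimated correlation). Serum amyloid genes are close paralogs, so their shares of reads are uncertain. Markers of macrophages and Kupffer cells, the other source of some of these transcripts, had a median log2 fold change of 0.04. In the list of interferon-stimulated genes, Oasl1 fell from 260.8 to 117.6 ± 10.9 RPKM and its relative Oasl2 rose from 22.01 to 39.5 ± 5.1 RPKM. The call of Oasl2 was lost with quantile normalization, median centring, no trend and voom (adjusted p = 0.0814, 0.0615, 0.105 and 0.056). That list had 1 member called higher, 1 lower and 22 not called, with 5 higher and 2 lower when adjusted over the list alone, and 22 of 24 fold changes were positive (median 0.27, camera adjusted p = 0.0202, adjusted p = 0.421 with an estimated correlation).

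Among 24 measured genes of xenobiotic oxidation and conjugation, 5 were called higher, none lower and 19 were not called. Fmo5 rose from 10.96 to 44.3 ± 1.7 RPKM, Nr1i2, which encodes the xenobiotic receptor PXR, from 5.09 to 20.4 ± 5.8 RPKM, Cyp3a11, a PXR target, from 29.8 to 77.5 ± 7.9 RPKM and the glucuronosyltransferase Ugt2b5 from 11.8 to 30.0 ± 7.8 RPKM. With adjustment over the list alone 7 were higher (median log2 fold change 0.44, camera adjusted p = 1.2e-08, adjusted p = 0.421 with an estimated correlation). Cyp and Ugt families hold near-identical members whose reads can be split. The list of NRF2 and glutathione response genes moved both ways, with Gstm3, Gsta4 (36.4 to 111.8 ± 39.7 RPKM) and Nfe2l2, which encodes NRF2 (80.4 to 144.5 ± 5.9 RPKM), higher and the sulfiredoxin gene Srxn1 lower (1216 to 644.7 ± 59.6 RPKM). Without the variance trend Nfe2l2 was not called (adjusted p = 0.0866). In this list 5 of 23 members were called higher, 2 lower and 16 not called, with 7 higher and 4 lower when adjusted over the list alone (median log2 fold change 0.26, camera adjusted p = 0.00249, adjusted p = 0.421 with an estimated correlation). The NRF2 list was not called with ranks or after the GC and length correction (adjusted p = 0.234 and 0.102), nor without the filter, and its median was 0.13 without TUDCA replicate 1 and 0.11 without TUDCA replicate 2.

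Of the genes of glucose metabolism, 3 of gluconeogenesis and glycogen were called higher and 1 of glycolysis lower. Pck1, G6pc (glucose-6-phosphatase, 0.500 to 5.99 and 2.55 RPKM) and Igfbp1 (57.5 to 117.8 and 75.8 RPKM) were the 3 of 15 gluconeogenesis and glycogen genes called higher, with none lower and 12 not called, and with 3 higher and 1 lower when adjusted over the list alone. The median log2 fold change was 0.29 (camera adjusted p = 0.00103, adjusted p = 0.421 with an estimated correlation). Without TUDCA replicate 1 the log2 fold change of G6pc was 1.24 in place of 1.73 and that of Igfbp1 0.39 in place of 0.71. By the smallest whole numbers that fit, G6pc had 13 reads in the DMSO library and Pck1 7. Quantile normalization, median centring, no trend and voom ended the call of Igfbp1 (adjusted p = 0.0843, 0.111, 0.221 and 0.0662). The aminotransferase Got1 had 149.4 RPKM in DMSO and 100.1 ± 7.4 with TUDCA (limma adjusted p = 0.144, and 0.0192 after the GC and length correction). Among 17 glycolysis genes, Pkm (pyruvate kinase of non-hepatic type) fell from 234.9 to 135.4 ± 15.8 RPKM, 16 were not called, and 1 was lower when adjusted over the list alone. Gapdh had 2610 RPKM in DMSO and 1848 ± 34 with TUDCA and was not called (limma adjusted p = 0.202), although quantile normalization called it and Eno1 lower (adjusted p = 2.5e-05 and 0.0353). The glycolysis list had 15 of 17 negative fold changes (median -0.29, camera adjusted p = 1.8e-04, adjusted p = 0.421 with an estimated correlation), and Pkm was not called without the variance trend (adjusted p = 0.121).

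In lipid metabolism, 5 of 25 measured members of the fatty acid oxidation and PPAR-alpha list were called higher, 1 lower and 19 were not called. The peroxisomal thiolase Acaa1b rose from 7.36 to 22.7 ± 1.6 RPKM, the pantetheinase Vnn1 from 11.3 to 29.3 ± 4.4 RPKM and the ketone body enzyme Bdh1 from 9.77 to 24.7 ± 7.0 RPKM. The counts of 5 and 1 were the same when adjusted over the list alone (median log2 fold change 0.16, camera adjusted p = 0.00562, adjusted p = 0.421 with an estimated correlation, adjusted p = 0.119 with ranks). The median of the list was 0.25 without TUDCA replicate 2. In the cholesterol synthesis and SREBP2 list no member of 25 was called by limma, over all genes or when adjusted over the list alone, and voom called none, while 2 were called after the GC and length correction (4 had an unadjusted limma p below 0.05). Still, 18 fold changes were negative and the list passed as a whole (median -0.19, camera adjusted p = 0.00444, adjusted p = 0.421 with an estimated correlation). Fdps, which makes farnesyl diphosphate, had 92.4 RPKM in DMSO and 65.5 ± 14.8 with TUDCA (limma adjusted p = 0.282). In the fatty acid and triglyceride synthesis list, Dgat2, which makes triglycerides, rose from 91.1 to 165.2 ± 8.8 RPKM, a call lost without the variance trend (adjusted p = 0.0759). The other 20 members were not called, 1 was higher when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.921).

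Among 26 measured cell cycle genes, 4 were called higher, none lower and 22 were not called. Cyclin D1 (Ccnd1) rose from 9.17 to 24.7 ± 4.4 RPKM, cyclin A2 (Ccna2) from 3.20 to 8.93 ± 0.59 RPKM, topoisomerase Top2a from 4.94 to 13.1 ± 3.8 RPKM and cyclin B1 (Ccnb1) from 1.91 to 4.76 ± 0.18 RPKM. With adjustment over the list alone 13 were higher and 1 lower, and 17 fold changes were positive and 9 negative (median 0.61, camera adjusted p = 9.6e-05, adjusted p = 0.421 with an estimated correlation). Ccnb1 was not called after rescaling to TPM, quantile normalization, median centring or voom (adjusted p = 0.0593, 0.111, 0.051 and 0.0592), and voom called Mki67 higher (adjusted p = 3.7e-04). Of the p53 and apoptosis list, the death receptor Fas rose from 6.27 to 16.3 ± 1.9 RPKM, while the cell cycle inhibitor Cdkn1a had 539.1 RPKM in DMSO and 376.4 ± 26.7 with TUDCA (limma adjusted p = 0.175, and 0.0439 after the GC and length correction). The other 22 members were not called, 2 were higher when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.518). Among 20 immediate early genes, Fos rose from 2.55 to 6.46 ± 0.81 RPKM, a call lost with quantile normalization and voom (adjusted p = 0.0628 and 0.0585). The other 19 were not called by limma, 2 were higher and 1 lower when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.586). Of these, Egr1 was called higher by voom and after the GC and length correction (adjusted p = 0.0459 and 0.00416), and Fosl1 lower with median centring and after that correction (adjusted p = 0.0424 and 0.00871).

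Among hepatocyte genes, the transcription factor Hnf4a rose from 115.0 to 194.9 ± 5.2 RPKM (limma adjusted p = 0.0123), a call lost with median centring and without the variance trend (adjusted p = 0.0568 and 0.160). Albumin (Alb) had 5771 RPKM in DMSO and 6644 ± 753 with TUDCA and was not called (adjusted p = 0.847). The list of secreted proteins and transcription factors had 1 of 27 members called higher by limma, 26 not called and 3 higher when adjusted over the list alone, with 23 positive fold changes (median 0.18, camera adjusted p = 0.0202, adjusted p = 0.421 with an estimated correlation). Apob was called higher by voom (adjusted p = 0.0486), and Trf with quantile normalization and after the GC and length correction (adjusted p = 0.00774 and 0.00828). In the urea cycle and amino acid breakdown list, Aass, which degrades lysine, rose from 3.13 to 9.95 ± 0.16 RPKM and Hgd, which degrades tyrosine, from 14.2 to 35.2 ± 5.3 RPKM, and 22 members were not called by limma. Cps1, the entry enzyme of the urea cycle, was missed by limma (adjusted p = 0.0587) and called higher by voom (0.00679), with a pseudocount of 0.1 (0.0448), without the variance trend (0.0342), with robust estimation (0.0441), at 300 nt and 20 reads (0.0444) and after the GC and length correction (0.0192). When adjusted over the list alone 5 were higher and 1 lower. That list did not pass (median 0.079, camera adjusted p = 0.106) and passed with quantile normalization (adjusted p = 0.0442). Its median was 0.050 without TUDCA replicate 1, 0.031 at 5 RPKM, 0.039 with median centring and 0.048 after the GC and length correction. Of 14 pericentral markers, the retinaldehyde dehydrogenase Aldh1a1 rose from 122.0 to 257.6 ± 46.1 RPKM, 13 were not called, and 3 were higher and 1 lower when adjusted over the list alone (median 0.42, camera adjusted p = 0.0113, adjusted p = 0.421 with an estimated correlation). Of 18 periportal markers, Pck1 and G6pc rose, 16 were not called by limma (Cps1 among them), and 4 were higher when adjusted over the list alone (median 0.05, camera adjusted p = 0.0172, adjusted p = 0.421 with an estimated correlation). The periportal call was lost with ranks, a filter of 5 RPKM and the GC and length correction (adjusted p = 0.433, 0.624 and 0.0681) and without the filter. Its median was -0.05 at 5 RPKM, 0.09 without TUDCA replicate 2, 0.12 with quantile normalization and 0.01 with median centring. Among 10000 random lists matched on expression that median stood at percentile 66.8.

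Genes of the cytoskeleton and of dedifferentiation moved both ways. Ccn2 fell from 140.1 to 54.5 ± 2.3 RPKM and the tubulin Tubb6 from 484.9 to 283.2 ± 7.2 RPKM, whereas osteopontin (Spp1) rose from 387.5 to 672.9 ± 133.9 RPKM. Tubb6 and Spp1 were not called without the variance trend (adjusted p = 0.141 and 0.134). Of 33 measured members, 1 was called higher, 2 lower and 30 not called, with the same counts when adjusted over the list alone (median -0.12, camera adjusted p = 0.0364, adjusted p = 0.421 with an estimated correlation). The list was not called with ranks, at 5 RPKM, with quantile normalization or after the GC and length correction (adjusted p = 0.134, 0.0805, 0.0957 and 0.104), nor without the filter, and its median stood at percentile 6.5 of the random lists. In the extracellular matrix and TGF-beta list, Ccn2 was the only member of 22 called, and 1 was lower when adjusted over the list alone (median -0.07, camera adjusted p = 0.0364, adjusted p = 0.613 with an estimated correlation). This call was lost with ranks, at 5 RPKM and after the GC and length correction (adjusted p = 0.0698, 0.0779 and 0.0968), and the median was -0.15 without TUDCA replicate 1, -0.17 with quantile normalization and -0.11 with median centring. It stood at percentile 5.1 of the random lists. Among 14 cytosolic heat shock genes, Hspb1 fell from 459.8 to 270.0 ± 44.9 RPKM, a call lost without the variance trend (adjusted p = 0.140), 13 were not called, and 1 was lower when adjusted over the list alone (median -0.19, camera adjusted p = 0.00513, adjusted p = 0.421 with an estimated correlation).

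No member was called in 3 further lists by limma, over all genes or when adjusted over the list alone, or by voom. An unadjusted limma p below 0.05 was found for 2 autophagy and lysosome genes and for 0 in the other lists of this group. These were 43 cytosolic ribosomal protein genes (median -0.02, camera adjusted p = 0.495), 33 nuclear-encoded genes of the respiratory chain (median 0.03, adjusted p = 0.921) and 24 genes of autophagy and lysosome (median -0.05, adjusted p = 0.438). The medians of the ribosomal and respiratory chain lists had opposite signs in the TUDCA libraries, at 0.066 and 0.072 without TUDCA replicate 1 and -0.119 and -0.045 without TUDCA replicate 2. Both also turned sign with some other settings. The median of the immediate early list turned from -0.049 to 0.031 without TUDCA replicate 1. The autophagy receptor Sqstm1 had 4472 RPKM in DMSO and 2930 and 4115 RPKM with TUDCA. The camera test pointed downward for the respiratory chain, fatty acid synthesis and macrophage lists, whose medians were slightly positive. Among random lists matched on expression the respiratory chain median stood at percentile 98.2, although camera did not call that list. All lists that camera called stood at or below percentile 1.8 or at or above 99.4, except the periportal, dedifferentiation and extracellular matrix lists.

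Markers of other liver cells were measured in the same libraries. Of 18 macrophage and Kupffer cell markers none was called by limma, over all genes or when adjusted over the list alone, none by voom, and 0 had an unadjusted limma p below 0.05 (median 0.04, 0.02 without TUDCA replicate 1 and -0.03 at 5 RPKM, camera adjusted p = 0.921), with Cd14 at 326.4 RPKM in DMSO and 426.2 ± 36.8 with TUDCA. The same held for 7 stellate cell and fibroblast markers (median -0.15, adjusted p = 0.241), where Dcn had 6.32 and 5.25 ± 0.70 RPKM, and for 7 sinusoidal endothelial markers (median 0.22, adjusted p = 0.921), where Stab1 had 15.5 and 10.7 ± 0.4 RPKM. Of 8 cholangiocyte markers, Bicc1 rose from 2.15 to 7.20 ± 0.24 RPKM, Spp1 rose, the claudin Cldn4 fell from 107.3 to 54.5 ± 3.8 RPKM, and 5 were not called, with 3 higher and 1 lower when adjusted over the list alone (median 0.43, camera adjusted p = 0.0230, adjusted p = 0.421 with an estimated correlation). This list was not called at 5 RPKM (adjusted p = 0.0813) or without the filter, and Prom1 was called higher by voom, without the variance trend and at 300 nt and 20 reads (adjusted p = 0.00523, 0.0486 and 0.0441). Only 2 lymphocyte and erythroid markers were measured and that list was not tested. Ccl5 had 183.6 RPKM in DMSO and 177.4 ± 3.7 with TUDCA, and Alas2 had 6.93 and 6.85 ± 0.50 RPKM.

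**Figure D3:**
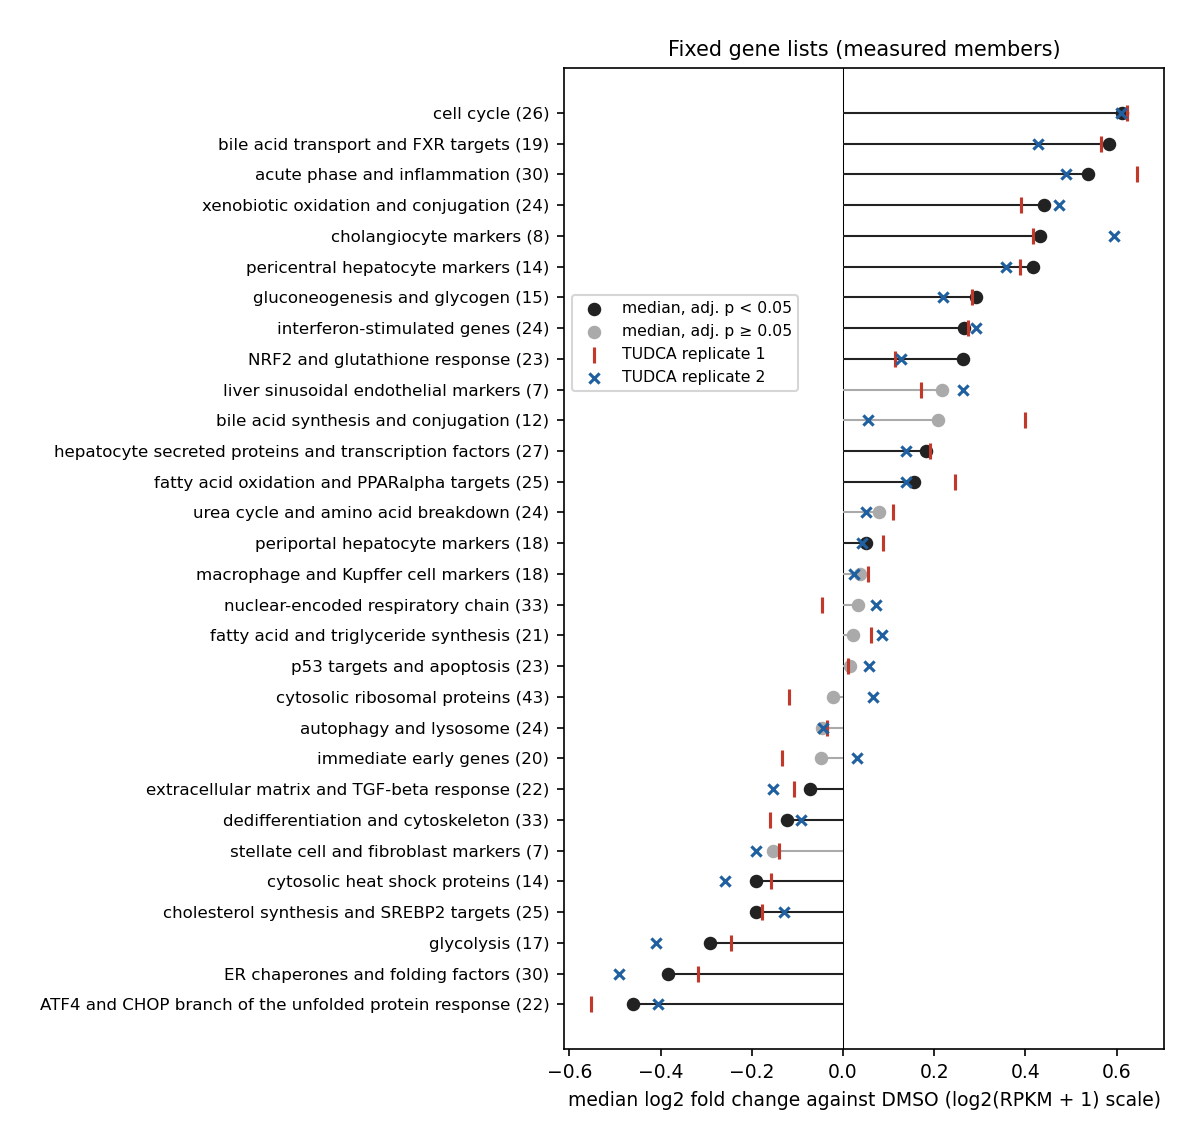
Median log2 fold change of 30 gene lists (x axis, log2(RPKM + 1) scale, number of measured members in parentheses), with circles for the mean of both TUDCA libraries against DMSO, black where camera's adjusted p was under 0.05 and grey otherwise, and marks for each TUDCA library. Cell cycle (0.61), bile acid transport (0.58) and acute phase genes (0.54) had the highest medians, and the ATF4 and CHOP branch (-0.46) and ER chaperones (-0.38) the lowest.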

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

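The mean SD of the fold changes from DMSO (0.389) became 0.512 with a pseudocount of 0.1 and 0.347 without a filter on low values, and 0.365 to 0.414 with 1 TUDCA library. The size rule (119 genes) gave 225 genes with a pseudocount of 0.1, 511 at a log2 limit of 0.58 and 188 to 284 with 1 TUDCA library. The 119 genes were among them in each case, which was fixed in advance since these settings can only add genes. The limma count (299 genes) was 0 without a filter, where 1696 genes had an unadjusted p below 0.05. The prior degrees of freedom fell from infinite to 1.11 there, and to 6.34 at an added filter of 0.3 RPKM, which called 26 genes, 20 of them among the 299. Against a fold change of 1.5 it was 57 (all among the 299), since that test asks for more than a difference from 0. It was 692 (424 higher, 268 lower, 294 of them among the 299) after the GC and length correction, added after seeing the data, and the cause was not tested. In the other settings it lay between 232 and 394, including 268 with the added voom fit (227 among the 299) and 274 with the added filter at 300 nt and 20 reads (258 among the 299). The lists called (19) numbered 0 with an estimated correlation (0 with an unadjusted p below 0.05, lowest 0.0532), which has 1 residual degree of freedom to estimate from, and 14 to 20 otherwise. Of 68 named genes called, 49 stayed called in the same direction in every setting that tested them, leaving aside the fit without a filter (which called none), the filter at 0.3 RPKM and the test against a fold change of 1.5. Of the 19 lists, 13 stayed called in every setting that tested lists but the estimated correlation. Leaving out 1 TUDCA library left no residual degree of freedom, so the limma and camera counts have no value there, and leaving out DMSO left no comparison. No paired analysis was possible because the DMSO label carries no replicate number. By the smallest lengths that fit, 31 of the 299 called genes were under 300 nt.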

Other observations

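Levels in all 3 libraries describe the state of the cultures, from genes partly chosen after their values were seen. Albumin was abundant (5771 RPKM in DMSO), whereas Cps1, the entry enzyme of the urea cycle, had 2.62 RPKM in DMSO and 5.79 and 6.08 RPKM with TUDCA, and Cyp7a1 had no read. The cornified envelope precursor Sprr1a ranked 4 among all genes in the DMSO library at 8877 RPKM and stood at 5591 and 5626 RPKM with TUDCA (log2 fold change -0.66 ± 0.20, limma adjusted p = 0.0388). The autophagy receptor Sqstm1, an NRF2 target, ranked 12 in DMSO at 4472 RPKM, and the NRF2 target Srxn1 ranked 69 at 1216 RPKM.

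The tests for macrophages, for epidermal genes as a set and for other groupings of the libraries were chosen after the results were seen, and the GC and length correction was an added setting. The real grouping gave 299 called genes, and setting TUDCA replicate 1 or TUDCA replicate 2 against the other 2 libraries gave 0 (617 with an unadjusted p below 0.05 by limma) and 8. The real grouping was the only 1 of the 3 that gave as many, but 3 groupings are too few for a share under 0.05. The other groupings paired DMSO with a TUDCA library, so the larger distance to DMSO entered their residual spread. Fewer calls there were thus largely fixed in advance. An odd DMSO culture would give the same order of counts, so they decide nothing about its cause.

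Acute phase genes were higher in both TUDCA libraries (median log2 fold change 0.538). A trend of the fold changes on GC content and gene length was argued against, since the median was 0.591 after its removal (camera adjusted p = 1.1e-16). More macrophages in the TUDCA cultures, as the source of these transcripts, were argued against by their markers, whose median was 0.038. If macrophages held the transcripts, the marker median would have had to move about as far as the acute phase genes. A rise of these genes in the hepatocytes themselves, whatever its trigger, is not covered by this test. The SE of the marker median (0.091) was taken across marker genes, which are not replicates, so it leaves out variation between cultures. The acute phase list's call was lost by camera with an estimated correlation (adjusted p = 0.421). A response to TUDCA and a chance state of the single DMSO culture both stay open, since DMSO was not replicated. So does a difference in time between the cultures, since the labels give no time for DMSO.

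Id1, Id2 and Id3, together with Hamp, Hamp2 and Atoh8, are known targets of BMP-SMAD signalling, a set chosen after seeing the values. Id1 rose from 31.2 RPKM in DMSO to 141.3 and 63.3 RPKM with TUDCA, Id3 from 88.6 to 300.6 and 201.9 RPKM, and Atoh8 from 1.66 to 22.8 and 6.87 RPKM (limma adjusted p = 3.3e-10, 3.2e-10 and 1.4e-13), each farther from DMSO in TUDCA replicate 1. A candidate explanation is a wider response of BMP-SMAD targets, tested on 6 other measured targets. Their median log2 fold change was 0.199 (SE 0.181 across genes, which are not replicates). The bound of 0.5 set before the test lay within 2 SE of this median, so a wider response was neither shown nor excluded. Smad7 (log2 fold change 0.00 ± 0.25) and Smad6 (0.43 ± 0.31) were not called. From 18.3 RPKM in DMSO, Smad7 went to 23.3 and 14.4 RPKM with TUDCA, and Smad6 from 1.92 to 4.42 and 1.84 RPKM. Smad9 and Bmper were also higher in TUDCA replicate 1 than in replicate 2, and Tmprss6 and Gata4 lower. Reads shared between the paralogs Hamp and Hamp2 stay open for that pair.

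Crct1, Lce1g and Lce1h, genes of the cornified envelope, were lower in both TUDCA libraries. A candidate source is skin cells in the DMSO culture, which would bring abundant keratins and loricrin. The highest of these in DMSO was Krt5 at 29.549 RPKM, 3.685% of Crct1 (801.9 RPKM), which lay between the upper and lower bounds set before the test, so that test was undecided. Whole epidermal cells, with their basal and suprabasal genes, were argued against by a list and a bound chosen after the values were seen. The outcome was known when that bound was set, so it is no independent test. Of 30 listed keratinocyte genes 21 had fewer than 3 reads in DMSO, by the smallest whole numbers that fit. Krt1, Krt14 and Trp63 had none. Krt10 (1.85 RPKM) had a log2 fold change of -0.05 ± 0.31. The other measured genes of the list all fell. Krt5, Lor, Sfn and Sprr1a were called lower (log2 fold change -0.93, -0.98, -0.90 and -0.66), and Sprr1b and Lce1f (-0.81 and -0.89) were not called. Expression of part of this programme by the cultured cells, a chance state of the DMSO culture and a difference in time between the cultures therefore stay open.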
